A study of Homo sapiens with 9 samples.

How the data were processed

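Gene expression was measured by RNA sequencing of human T778 liposarcoma cells in 9 libraries, 3 untreated, 3 treated with EML631 and 3 transfected with siRNA against SPIN1. Group and replicate number were taken from the sample titles, and the columns of the tables were matched to samples by name. Column names call the knockdown a knockout; the titles and treatment labels describe siRNA, and knockdown is used throughout.

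The authors deposited 1 table of estimated counts per gene and 1 table of FPKM values, each with 28503 rows. The submitters' processing notes list TopHat2 2.0.12, Cuffdiff, edgeR 3.12.0 and the genome build hg19, without saying what each was used for. Annotation, strand handling and treatment of fragments that match several genes are not given in the sources used here. The deposited counts behave as a signal scaled between libraries: the low values of a library are multiples of 1 step, which lies between 0.894 and 1.2 depending on the library, and the totals are nearly equal. Of values up to 20 steps, 92.9% to 93.9% were whole multiples within 0.01 of a step; the others are fractional, as estimates that divide fragments between genes would be. They were therefore not treated as raw counts. The deposited FPKM values carry the same scaling.

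Of the rows, 28 had no usable gene name, 27 of them because a spreadsheet had turned symbols into dates. They held 0.303% to 0.315% of each library's total and were left out, leaving 28475 genes. The files give gene symbols and no coordinates, and the reference annotation at hand is of another genome build, so no positions are reported. Scaled totals were 24707863 to 25102929 per library, and totals divided by the step were 20720015 to 27904129 fragments.

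The planned edgeR quasi-likelihood test was not run, because the deposited values turned out to be scaled. The plan foresaw limma on log2 values for that case. Values were transformed as log2(scaled count + 1), and 15774 genes with a scaled count of at least 10 in at least 3 libraries were kept; pseudocount and filter were set once the unit was known. Fold changes are on that scale and understate changes of low genes. One model with the 3 groups was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3, with trended and robust empirical Bayes moderation and 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over genes within each comparison. A gene was called at an adjusted p below 0.05. Levels are given as CPM, computed from the scaled counts of named genes. With 3 libraries against 3, an exact permutation test of a single gene could not go below 0.1. The labels give no batch.

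Before the data were examined, 33 gene lists and the rule for named genes were fixed. The rule takes, per comparison, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 5 CPM and groups that do not overlap, up to 4 members with the smallest adjusted p of each list described, and SPIN1, SPIN2A, SPIN2B, SPIN3, SPIN4, GDNF, RET and MAZ. For the shared response it takes the 6 genes up in both, the 6 down in both and the 4 of opposite sign with the smallest larger adjusted p. XIST, Y-linked genes and rows naming several genes were left out. Some genes that the rule names are not reported here. Lists with at least 3 tested genes, 32 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The list of mitochondrially encoded genes had 0 members in the table. Camera called 16, 14 and 9 lists for EML631, the knockdown and the direct comparison, and 0 of these held with an estimated correlation, which with few libraries is imprecise. The fry test, which asks whether the genes of a list move on balance in one direction and compares them with no other genes, called 22, 17 and 14 lists, including all of camera's.

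Perturbations set against the same controls share their chance values. Correlations and the covariance of fold changes are therefore given beside 100 simulations of 3 unchanged groups with each gene's own spread. The whole procedure was also tested on simulated data in which known genes were changed. For EML631 against control, with 15639 simulated genes, it recovered 55.9% of genes changed 1.25-fold, 76.5% of those changed 1.5-fold and 87.5% of those changed 2-fold, and 5.81% of its calls were false. For the knockdown, with 15646 genes, these shares were 52.8%, 80%, 91.2% and 7.5%, and for the direct comparison, with 15638 genes, 62.7%, 80.3%, 86.4% and 7.93%. The simulations changed few genes, and 155 to 164 were called, against 3353 to 3489 in the data. The adjusted p is stricter when few genes change, so the recovered shares may understate those in the data. Each gene was drawn independently of the others, with no effect of culture or handling, so the false shares do not cover such effects.

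Alternatives that were tried are no filter on low counts, a fit of the 6 libraries compared, the replicate number as a block, leaving out each library, and the FPKM table with pseudocounts of 1 and 0.1 and without its filter (mean of at least 1). Added after the data were seen were scaling to equal totals, quantile normalization, pseudocounts of 0.5 and 10, and voom weights on values divided by the step. GC content was taken from the longest transcript per symbol in a reference annotation, and length from the ratio of deposited count to FPKM. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.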

Results

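RNA was sequenced from T778, an established human liposarcoma cell line, in 3 groups of 3 libraries. The first group was left untreated. The second received EML631, a small-molecule inhibitor of SPIN1, for 3 days at a dose that the labels give as 10 mM; the unit could not be checked from the data. The third received 15 nM of small interfering RNA against SPIN1 with a lipid transfection reagent for 24 hours. SPIN1 (Spindlin1) is a chromatin protein that reads methylated histone H3 tails. The comparisons ask what the inhibitor and the depletion of its target each change, and which genes answer to both. Neither a non-targeting siRNA group nor a vehicle group is among the samples, so transfection and solvent are part of each comparison with the controls. The labels do not say whether libraries of a group came from separate cultures, and p-values then measure only the spread between these libraries.

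The scaled totals lay between 24707863 and 25102929 per library, and the estimated depth before scaling between 20720015 and 27904129 fragments. Replicates of a group correlated at 0.992 to 0.993 across genes on the log2 scale, and each pair differed by more than counting noise, with a chi-square per gene of 1.93 to 9.65. The highest values came from the pairs with control replicate 3. The first principal component held 21.1% of the variance and set the EML631 libraries, at 13.9 to 20.8, apart from all others. The second component held 18.3%. Along it the controls lay at 12.5 to 15.7, the EML631 libraries at -2.04 to 4.94 and the knockdown libraries at -18.2 to -12.6.

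SPIN1 was lowest in the knockdown, at 70.3 ± 29.3 CPM (SD, n = 3) against 144 ± 4.19 in the controls. The siRNA libraries held 40.1%, 72.2% and 34.3% of the control mean, in the order of their replicate numbers, so replicate 2 kept the most SPIN1. All 3 lay below all 3 controls. The log2 fold change was -1.12 (SE 0.268) and limma's adjusted p was 0.0288. This call rests on a wide spread within the knockdown group. Without replicate 2 the log2 fold change was -1.45 with an adjusted p of 2.83e-09, whereas leaving out any one of the other 8 libraries gave adjusted p between 0.0519 and 0.0992. With the 6 libraries of the comparison alone it was 0.0946. EML631 libraries held 98.6 ± 5.95 CPM (SD, n = 3), or 65% to 73.1% of the control mean, again below every control. Their log2 fold change of -0.56 (SE 0.268) did not pass, with an adjusted p of 0.213. Fitted with the 6 libraries of that comparison alone, whose spread was narrower, SPIN1 had an adjusted p of 1.05e-10. EML631 and the knockdown differed by 0.57 in log2 (adjusted p = 0.207). Without knockdown replicate 2 this was 0.888 (adjusted p = 4.49e-07), and without replicate 3 it was 0.347 (adjusted p = 0.434). Among the paralogs, SPIN4 was higher with EML631 than in the controls, at 26.1 ± 0.603 against 19 ± 0.659 CPM (log2 fold change 0.45, SE 0.0643, adjusted p = 8.12e-06), and had a log2 fold change of 0.08 in the knockdown (adjusted p = 0.439). SPIN3 and SPIN2B passed in neither comparison, and SPIN2A was below the minimum count. Spindlins are close paralogs, and fragments may have been divided between them.

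**Figure D1:**
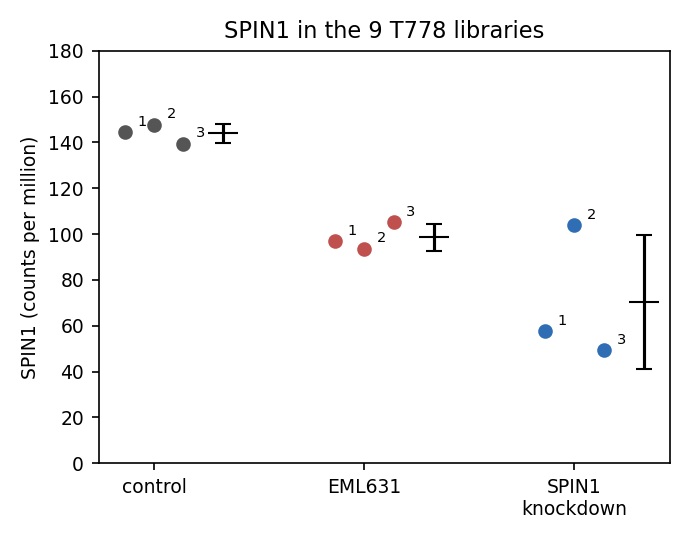
SPIN1 in CPM in each of the 9 libraries (points, numbered by replicate) with the mean and SD of each group of 3 (black bars). All EML631 and knockdown libraries lie below the controls, and knockdown replicate 2, at 72.2% of the control mean, lies near the EML631 libraries.

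Against untreated cells, interferon-stimulated and inflammatory genes were lower with EML631, and genes of DNA replication and mitosis were higher. All 41 tested interferon-stimulated genes fell (41 adjusted over the list alone), with a median log2 fold change of -0.72. Camera gave an adjusted p of 2.4e-52 with its preset correlation, and the adjusted p = 0.109 with an estimated correlation. The smallest adjusted p-values of the list belonged to MX2 (log2 fold change -0.75, SE 0.0439), DDX58, the cytosolic RNA sensor RIG-I (-0.72, SE 0.0441), PARP14 (-0.58, SE 0.0361) and the antiviral GTPase MX1 (-1.01, SE 0.0481). Of 27 NF-kB and cytokine genes, 22 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.55). For NF-kB genes camera gave an adjusted p of 7.72e-27, and the adjusted p = 0.051 with an estimated correlation. CXCL1 fell by 1.02, ICAM1 by 0.58, CSF2 by 0.98 and PTGS2, the inducible cyclooxygenase, by 0.62 on the log2 scale. Antigen presentation fell as well, with 12 of 15 genes lower and 0 higher (12 and 0 adjusted over the list alone). For antigen presentation camera gave an adjusted p of 1.54e-08, and the adjusted p = 0.146 with an estimated correlation. HLA-E fell by 0.36 and B2M, the light chain of class I molecules, by 0.24.

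Cell cycle genes moved up with EML631. All 40 G2/M and mitosis genes rose (40 adjusted over the list alone; median log2 fold change 0.41), among them FOXM1 (0.52, SE 0.0482), CDC25B (0.39, SE 0.0406) and BIRC5 (0.42, SE 0.0458). For G2/M genes camera gave an adjusted p of 6.22e-33, and the adjusted p = 0.146 with an estimated correlation. G1/S and DNA replication genes rose in 36 of 40 cases and fell in 0 (38 and 0 adjusted over the list alone; median 0.33), including CLSPN (0.58, SE 0.0463), UHRF1 (0.40, SE 0.0352) and RRM2, a subunit of ribonucleotide reductase (0.47, SE 0.0399). For G1/S genes camera gave an adjusted p of 7.72e-27, and the adjusted p = 0.146 with an estimated correlation. Histone genes rose in 23 of 27 cases and fell in 0 (23 and 0 adjusted over the list alone), HIST1H3B by 0.63 in log2. For histone genes camera gave an adjusted p of 2.1e-16, and the adjusted p = 0.146 with an estimated correlation. Histone genes have near-identical copies, and which copy changed is uncertain. Heat shock genes were higher in 14 of 20 cases and lower in 0 (17 and 1 adjusted over the list alone), with FKBP4 up by 0.38. For heat shock genes camera gave an adjusted p of 8.29e-09, and the adjusted p = 0.146 with an estimated correlation. RNA polymerase I and rRNA processing genes were higher in 13 of 28 cases and lower in 1 (14 and 1 adjusted over the list alone), with NOLC1 up by 0.26. For RNA polymerase I genes camera gave an adjusted p of 0.000239, and the adjusted p = 0.151 with an estimated correlation.

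Hypoxia and glycolysis genes fell in 22 of 32 cases with EML631 and rose in 0 (23 and 1 adjusted over the list alone; median -0.20). For hypoxia genes camera gave an adjusted p of 5.2e-11, and the adjusted p = 0.174 with an estimated correlation. ADM, encoding adrenomedullin, fell by 0.54 and VEGFA by 0.31 on the log2 scale. Lysosomal genes fell in 25 of 43 cases and rose in 0 (25 and 0 adjusted over the list alone), with SQSTM1, an autophagy receptor, down from 1218 ± 4.84 to 948 ± 16.5 CPM (SD, n = 3). For lysosomal genes camera gave an adjusted p of 3.91e-10, and the adjusted p = 0.074 with an estimated correlation. YAP/TEAD targets were higher in 12 of 21 cases and lower in 2 (15 and 2 adjusted over the list alone), led by TGFB2 (0.65, SE 0.0406) and F3, tissue factor (0.45, SE 0.0424). For YAP/TEAD targets camera gave an adjusted p of 2.69e-07, and the adjusted p = 0.123 with an estimated correlation. Wnt targets were higher in 5 of 16 cases and lower in 0 (6 and 0 adjusted over the list alone), among them MYC (0.35, SE 0.0583). For Wnt targets camera gave an adjusted p of 0.00389, and the adjusted p = 0.345 with an estimated correlation. TGF-beta targets were higher in 7 of 20 cases and lower in 2 (9 and 2 adjusted over the list alone); that list shares TGFB2 with the YAP/TEAD list, and TGFBI fell by 0.27. For TGF-beta targets camera gave an adjusted p of 0.0126, and the adjusted p = 0.366 with an estimated correlation. Matrix metalloproteinases and inhibitors were lower in 8 of 18 cases and higher in 2 (9 and 4 adjusted over the list alone), with MMP14 down by 0.25. For metalloproteinases camera gave an adjusted p of 0.0168, and the adjusted p = 0.357 with an estimated correlation. The call was lost without control replicate 1 (adjusted p = 0.0539) and on the filtered FPKM table with pseudocounts of 1 (0.0659) and 0.1 (0.0658). Cholesterol synthesis genes were lower in 5 of 28 cases and higher in 2 (7 and 2 adjusted over the list alone), led by INSIG1 (-0.48, SE 0.0487). For cholesterol synthesis camera gave an adjusted p of 0.0192, and the adjusted p = 0.366 with an estimated correlation. That call was lost without control replicate 3 (adjusted p = 0.0596) and without EML631 replicate 3 (0.0595). Targets of p53 were lower in 7 of 30 cases and higher in 0 (7 and 0 adjusted over the list alone), with GDF15 at -0.74 (SE 0.0466). For p53 targets camera gave an adjusted p of 0.032, and the adjusted p = 0.357 with an estimated correlation. The p53 call was lost without EML631 replicate 2 (adjusted p = 0.126), without control replicate 3 (0.0848), under quantile normalization (0.0526) and on the filtered log2(FPKM + 1) (0.0501).

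Among called genes with a mean of at least 5 CPM and groups that did not overlap, the largest increases with EML631 were in TAGLN, an actin-binding protein of smooth muscle, from 11.9 ± 1.7 to 26.3 ± 1.64 CPM (SD, n = 3; log2 fold change 1.14), and MYL9, a myosin light chain (0.81), followed by HIST1H3J, ARHGAP33, HIST1H3I, E2F2, INHBB and NRXN3 at 0.71 to 0.81. Within the same limits, the largest decreases were in the chemokine CXCL11 (-1.38), IL8 (-1.36), IL1B, from 38.3 ± 1.66 to 15.3 ± 1.83 CPM (SD, n = 3; -1.34), IFI44L (-1.21), IFIT1 (-1.04), RSAD2 and CXCL2 (both -1.03) and CHRNA1 (-1.03). MAZ, a zinc finger transcription factor, was at 63.9 ± 1.66 CPM against 49.4 ± 4.31 (SD, n = 3; log2 fold change 0.36, adjusted p = 1.42e-05). GDNF had a log2 fold change of 0.02 (adjusted p = 0.868). Its receptor RET was below the minimum count, and the co-receptor GFRA1 rose by 0.18 (SE 0.0284, adjusted p = 2.37e-05). In all, 3489 of 15774 genes passed limma's adjusted p of 0.05, 1739 higher and 1750 lower. Most changes were small: 107 of the higher and 170 of the lower genes exceeded 1.5-fold, and 15 and 37 exceeded 2-fold. Over all tested genes, groups did not overlap for 36.5%, where chance gives 10%.

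Lists that camera did not call with EML631 had adjusted p from 0.0628 to 0.969. Collagens and extracellular matrix went both ways, with 8 genes higher, such as THBS1, and 9 lower of 28 (10 and 10 adjusted over the list alone). So did the MAPK feedback genes, with 4 higher and 5 lower of 24 (5 and 6), and the amino acid response, with 6 and 6 of 35 (6 and 6). Counts of higher and lower genes, followed by those adjusted over the list alone, were 2 and 6 of 27 (2 and 6) for the 12q13-15 amplicon that marks this tumour type, 3 and 5 of 21 (3 and 5) for fatty acid synthesis, 2 and 4 of 12 (2 and 5) for adipocyte differentiation, 2 and 1 of 25 (2 and 1) for the unfolded protein response and 3 and 5 of 25 (3 and 5) for NRF2 targets. They were 0 and 0 of 8 (0 and 0) for metallothioneins, 1 and 0 of 13 (1 and 0) for RNA interference machinery, 4 and 0 of 20 (4 and 0) for histone methylation enzymes, 2 and 0 of 6 (2 and 0) for GDNF-RET signalling and 1 and 0 of 4 (1 and 0) for the spindlins. Markers of other cell types gave 0 and 1 of 9 (0 and 1) for epithelial, 0 and 1 of 8 (0 and 1) for blood and endothelial and 0 and 2 of 5 (0 and 2) for muscle and neural genes.

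In the SPIN1 knockdown, interferon-stimulated, inflammatory and antigen presentation genes were also lower than in untreated cells, and cell cycle genes were higher. In addition, extracellular matrix genes were lower and glycolytic genes higher. Interferon-stimulated genes fell in 38 of 41 cases and rose in 0 (40 and 0 adjusted over the list alone; median log2 fold change -0.44), with MX2 at -0.54 (SE 0.0439) and IFI27 at -0.62 (SE 0.047). For interferon-stimulated genes camera gave an adjusted p of 1.49e-32, and the adjusted p = 0.11 with an estimated correlation. NF-kB and cytokine genes fell in 23 of 27 cases and rose in 0 (24 and 0 adjusted over the list alone; median -0.40), led by CCL2 (-0.76, SE 0.0455), TNFAIP3, a feedback inhibitor of NF-kB (-0.50, SE 0.0349) and IL32 (-0.68, SE 0.0476). For NF-kB genes camera gave an adjusted p of 8.84e-23, and the adjusted p = 0.0788 with an estimated correlation. Antigen presentation genes fell in 14 of 15 cases and rose in 0 (14 and 0 adjusted over the list alone), with HLA-B at -0.47; class I genes are close paralogs and may share fragments. For antigen presentation camera gave an adjusted p of 3.26e-14, and the adjusted p = 0.11 with an estimated correlation.

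All 40 G2/M and mitosis genes rose in the knockdown (40 adjusted over the list alone; median 0.50), with BIRC5 up by 0.52, TPX2 by 0.44 and CDC20 by 0.49. For G2/M genes camera gave an adjusted p of 1.06e-38, and the adjusted p = 0.11 with an estimated correlation. G1/S and DNA replication genes rose in 39 of 40 cases and fell in 0 (39 and 0 adjusted over the list alone; median 0.36), with the replicative helicase subunits MCM7 up by 0.41 and MCM5 by 0.39. For G1/S genes camera gave an adjusted p of 5.8e-31, and the adjusted p = 0.11 with an estimated correlation. Histone genes rose in 24 of 27 cases and fell in 0 (24 and 0 adjusted over the list alone), HIST1H4C by 0.52. For histone genes camera gave an adjusted p of 4.5e-18, and the adjusted p = 0.11 with an estimated correlation. Rises also covered 14 of 28 RNA polymerase I and rRNA processing genes, with 0 lower (15 and 0 adjusted over the list alone), with NCL up by 0.22. For RNA polymerase I genes camera gave an adjusted p of 1.12e-05, and the adjusted p = 0.11 with an estimated correlation. Heat shock genes were higher in 11 of 20 cases and lower in 3 (11 and 3 adjusted over the list alone), with HSPD1 up by 0.33 and SERPINH1, a collagen chaperone, down by 0.22. For heat shock genes camera gave an adjusted p of 0.00905, and the adjusted p = 0.496 with an estimated correlation. RNA interference machinery genes were higher in 3 of 13 cases and lower in 0 (3 and 0 adjusted over the list alone). For RNA interference camera gave an adjusted p of 0.0315, and the adjusted p = 0.337 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.0688) and without knockdown replicate 3 (0.115).

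Hypoxia and glycolysis genes rose in 22 of 32 cases in the knockdown and fell in 1 (26 and 2 adjusted over the list alone; median 0.20). For hypoxia genes camera gave an adjusted p of 4.48e-12, and the adjusted p = 0.15 with an estimated correlation. GAPDH rose by 0.25, the hexokinase HK2 by 0.40, TPI1 by 0.32 and ENO1 by 0.21 on the log2 scale. Cholesterol synthesis genes rose in 13 of 28 cases and fell in 2 (13 and 2 adjusted over the list alone), with FDFT1, squalene synthase, up by 0.27. For cholesterol synthesis camera gave an adjusted p of 0.00052, and the adjusted p = 0.271 with an estimated correlation. Collagens and extracellular matrix genes fell in 17 of 28 cases and rose in 0 (17 and 0 adjusted over the list alone; median -0.15), with LUM at -0.65 (SE 0.0403), FBN1 at -0.44 (SE 0.0337) and SPARC at -0.30 (SE 0.0246). For matrix genes camera gave an adjusted p of 3.96e-10, and the adjusted p = 0.11 with an estimated correlation. Matrix metalloproteinases and inhibitors fell in 9 of 18 cases and rose in 0 (13 and 0 adjusted over the list alone), with MMP2 at -0.50. For metalloproteinases camera gave an adjusted p of 1.79e-07, and the adjusted p = 0.11 with an estimated correlation. Lysosomal genes fell in 23 of 43 cases and rose in 1 (24 and 2 adjusted over the list alone), with SQSTM1 at -0.28 (SE 0.025). For lysosomal genes camera gave an adjusted p of 9.7e-08, and the adjusted p = 0.11 with an estimated correlation.

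Among called genes with a mean of at least 5 CPM and groups that did not overlap, the largest decreases in the knockdown were in IL1B, at 17.4 ± 3.96 against 38.3 ± 1.66 CPM (SD, n = 3; log2 fold change -1.17), CYP1B1, a dioxin-inducible cytochrome P450, at 20.7 ± 0.834 against 45.8 ± 1.49 CPM (SD, n = 3; -1.16), and SPIN1, followed by MEGF6 (-0.96), GRIN2A (-0.94), SLC15A3 (-0.91), FOXQ1 (-0.89) and NREP (-0.89). Within the same limits, the largest increases were in ZNF367 (0.76), SDPR (0.73), E2F2 (0.70), HIST1H1D (0.67), MCM10 (0.67), EPR-1 (0.64), HIST1H2BB (0.63) and HMGB2 (0.62). EPR-1 lies antisense to BIRC5, and without known strand handling reads of the pair cannot be told apart. MAZ rose by 0.30 (SE 0.0516, adjusted p = 0.000123). GDNF had a log2 fold change of -0.16 (adjusted p = 0.0798); it passed without knockdown replicate 2 (adjusted p = 0.0166) or without control replicate 3 (0.0153). GFRA1 fell by 0.22 (SE 0.0284). Limma called 3353 of 15774 genes, 1627 higher and 1726 lower, of which 59 and 178 exceeded 1.5-fold and 10 and 27 exceeded 2-fold. Over all tested genes, groups did not overlap for 34.5%, where chance gives 10%.

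Camera left 18 lists uncalled in the knockdown, with adjusted p from 0.054 to 0.91. Counts of higher and lower genes, followed by those adjusted over the list alone, were 4 and 3 of 21 (4 and 5) for YAP/TEAD targets, 3 and 3 of 20 (4 and 4) for TGF-beta targets, 3 and 0 of 16 (3 and 0) for Wnt targets, 7 and 2 of 24 (7 and 2) for MAPK feedback genes, 3 and 6 of 30 (3 and 6) for p53 targets and 5 and 3 of 27 (5 and 5) for the 12q13-15 amplicon. They were 10 and 2 of 21 (10 and 4) for fatty acid synthesis, where FASN rose by 0.41 and SCD by 0.58, 2 and 1 of 12 (2 and 1) for adipocyte differentiation, 1 and 6 of 25 (1 and 6) for the unfolded protein response, 9 and 4 of 35 (11 and 8) for the amino acid response, 2 and 4 of 25 (2 and 4) for NRF2 targets and 2 and 1 of 8 (4 and 2) for metallothioneins. Histone methylation enzymes gave 2 and 2 of 20 (2 and 3), GDNF-RET signalling 1 and 2 of 6 (2 and 3), spindlins 0 and 1 of 4 (0 and 1), epithelial markers 1 and 0 of 9 (1 and 0), blood and endothelial markers 0 and 1 of 8 (0 and 1) and muscle and neural markers 0 and 0 of 5 (0 and 0).

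**Figure D2:**
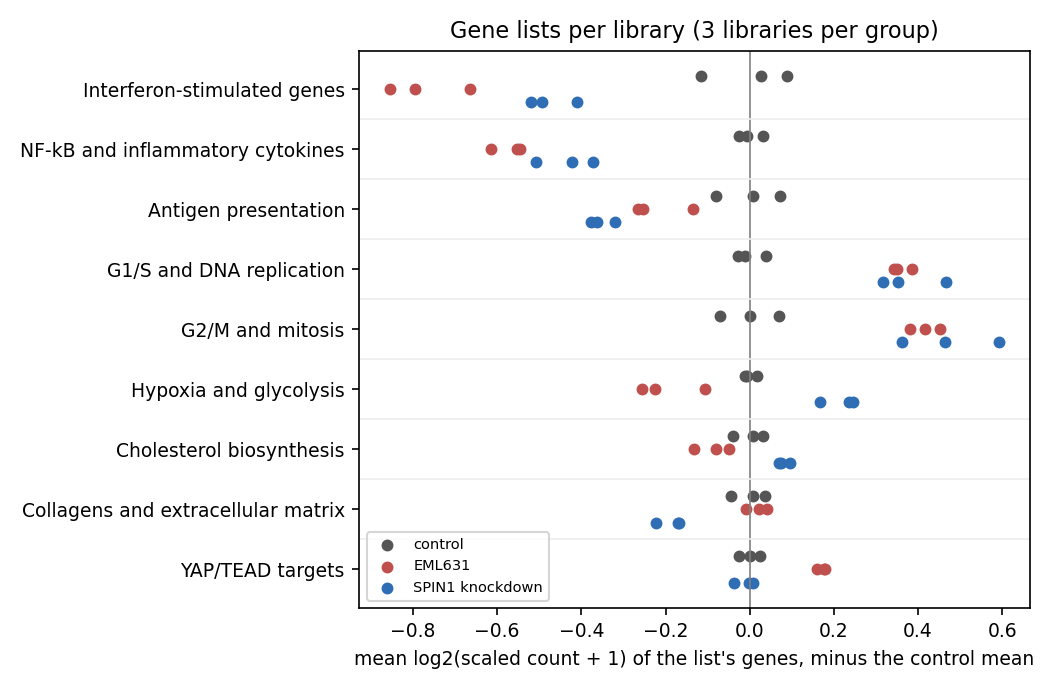
Mean log2(scaled count + 1) of the genes of 9 lists in each library, minus the mean of the 3 controls; each point is a library of the untreated (grey), EML631 (red) or SPIN1 knockdown (blue) group. Interferon-stimulated and NF-kB genes lie below the controls and cell cycle genes above them in both treated groups, whereas hypoxia and glycolysis genes lie on opposite sides.

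Both treatments called 752 genes higher and 729 lower, against 179 and 191 that independent lists of these sizes would share. Another 99 genes were higher with EML631 and lower in the knockdown, and 110 the reverse, against 190 and 181 for independent lists. These 209 genes of opposite direction became 119 to 247 with 1 library left out. The fold changes of the 2 comparisons correlated across genes with Pearson's r = 0.486 and Spearman's rho = 0.437; genes are not independent replicates, and simulated unchanged groups gave 0.5 and 0.447 from the shared controls alone. The covariance was 0.0303, against 0.0161 in the simulations with a range of 0.0127 to 0.0245. With 3 controls these could not be divided between the comparisons with at least 2 each, and part of the excess overlap may come from the shared controls.

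Genes raised most reliably by both were UHRF1, FAM111B, LMO7, CLSPN, TROAP and KIFC1. FAM111B went from 40.1 ± 1.23 CPM in the controls to 58.2 ± 1.38 with EML631 and 58.8 ± 3.87 in the knockdown (SD, n = 3). Genes lowered by both were AKR1B1, TNFAIP3, MX2, CCL2, TNFSF10 and SQSTM1. AKR1B1, an aldose reductase, went from 206 ± 3.78 CPM to 144 ± 3.47 with EML631 and 148 ± 1.99 in the knockdown (SD, n = 3). Opposite changes were clearest for THBS1, GFRA1, SERPINH1 and HMGA2. THBS1, a matrix glycoprotein, was at 6424 ± 112 CPM in the controls, 7784 ± 156 with EML631 and 5434 ± 171 in the knockdown (SD, n = 3); under quantile normalization its calls were lost, with adjusted p of 0.359 for EML631 and 0.333 for the knockdown. HMGA2, an architectural chromatin protein encoded in the amplicon, went from 307 ± 8.15 to 272 ± 7.96 CPM with EML631 and to 360 ± 7.31 in the knockdown (SD, n = 3).

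**Figure D3:**
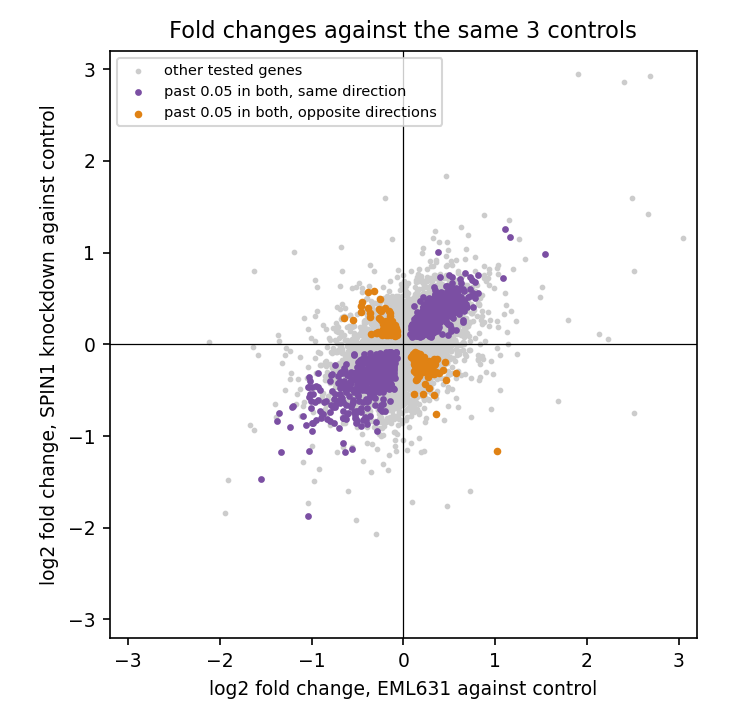
Log2 fold changes of all tested genes with EML631 (horizontal) and SPIN1 knockdown (vertical), both against the same 3 controls; 6 genes lie outside the axes. Purple points passed an adjusted p of 0.05 in both comparisons with the same direction and orange points with opposite directions.

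EML631 and the knockdown were then set against each other. They differ in time as well, 3 days against 24 hours. Transfection and any solvent are part of this comparison too. Hypoxia and glycolysis genes were lower with EML631 in 27 of 32 cases and higher in 0 (30 and 0 adjusted over the list alone; median log2 difference -0.39). For hypoxia genes camera gave an adjusted p of 2.97e-28, and the adjusted p = 0.182 with an estimated correlation. LDHA, lactate dehydrogenase A, was at 1210 ± 105 CPM with EML631 and 2039 ± 45.2 in the knockdown (SD, n = 3), and GAPDH, ADM, HK2 and ENO1 differed by -0.38, -0.67, -0.60 and -0.30 in log2. Cholesterol synthesis genes were lower with EML631 in 18 of 28 cases and higher in 3 (19 and 3 adjusted over the list alone; median -0.20), led by HMGCS1 (-0.39, SE 0.0367). For cholesterol synthesis camera gave an adjusted p of 1.08e-07, and the adjusted p = 0.22 with an estimated correlation. Fatty acid synthesis followed, lower in 8 of 21 cases and higher in 2 (10 and 3 adjusted over the list alone), with FASN at -0.30. For fatty acid synthesis camera gave an adjusted p of 0.00392, and the adjusted p = 0.195 with an estimated correlation. Interferon-stimulated genes were lower with EML631 than in the knockdown in 29 of 41 cases and higher in 0 (33 and 0 adjusted over the list alone; median -0.29), with OASL at -0.62 (SE 0.0714) and MX1 at -0.47 (SE 0.0481). For interferon-stimulated genes camera gave an adjusted p of 1.3e-17, and the adjusted p = 0.318 with an estimated correlation. NF-kB and cytokine genes were lower in 10 of 27 cases and higher in 5 (10 and 5 adjusted over the list alone); CXCL1 differed by -0.62 and IL32 by 0.64. For NF-kB genes camera gave an adjusted p of 0.0288, and the adjusted p = 0.581 with an estimated correlation. That list call was lost without EML631 replicate 1 (adjusted p = 0.113), without knockdown replicate 2 (0.0684) and on the filtered log2(FPKM + 1) (0.0504).

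Collagens and extracellular matrix genes were higher with EML631 than in the knockdown in 16 of 28 cases and lower in 1 (16 and 1 adjusted over the list alone; median 0.17), with SPARC at 0.32 and COL5A1 at 0.40. For matrix genes camera gave an adjusted p of 2.36e-09, and the adjusted p = 0.22 with an estimated correlation. YAP/TEAD targets were higher in 13 of 21 cases and lower in 1 (14 and 1 adjusted over the list alone), TGFB2 by 0.62 and ANKRD1 by 0.33. For YAP/TEAD targets camera gave an adjusted p of 7.14e-08, and the adjusted p = 0.182 with an estimated correlation. TGF-beta targets were higher in 12 of 20 cases and lower in 3 (12 and 5 adjusted over the list alone), PMEPA1 by 0.36. For TGF-beta targets camera gave an adjusted p of 0.00347, and the adjusted p = 0.581 with an estimated correlation. Antigen presentation genes were higher in 7 of 15 cases and lower in 1 (7 and 1 adjusted over the list alone), with HLA-B at 0.30. For antigen presentation camera gave an adjusted p of 0.00362, and the adjusted p = 0.581 with an estimated correlation. Of the cell cycle lists, G2/M genes were lower with EML631 in 3 of 40 cases and higher in 0 (2 and 0 adjusted over the list alone; median -0.06; camera adjusted p = 0.0586), and 18 of 40 were lower when knockdown replicate 2 was left out. G1/S genes were higher in 2 of 40 cases and lower in 3 (1 and 3 adjusted over the list alone). Histone genes were higher in 2 of 27 cases and lower in 1 (1 and 1 adjusted over the list alone). With all libraries, the cell cycle lists thus rose against the untreated controls in both treatments and differed little between them. Handling or culture state that the controls did not share cannot be told apart from the treatments for these lists.

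Among called genes with a mean of at least 5 CPM and groups that did not overlap, the largest single differences in favour of EML631 were in CDR1 (log2 difference 1.21, adjusted p = 0.0406), TAGLN (1.14), PTGIS, prostacyclin synthase (1.12), SHISA2 (1.08), CYP1B1 (1.08), MYL9 (0.97), SHANK2 (0.89) and TRIM58 (0.89). CDR1 lost its call when any single EML631 library was left out, with adjusted p from 0.0724 to 0.127, and also without knockdown replicate 1 (0.13), knockdown replicate 3 (0.113) or control replicate 2 (0.0543), and with no filter on low counts (0.0548). Within the same limits, those in favour of the knockdown were BNIP3, a hypoxia-induced mitophagy receptor (-0.95), MAL (-0.94), DKFZp547K2416 (-0.91), the stearoyl-CoA desaturase SCD (-0.91), SPP1 (-0.82), PPFIA4 (-0.81), RIMKLA (-0.78) and LDHA (-0.75). GDNF was higher by 0.18 (adjusted p = 0.0461), a call lost when any of several single libraries was left out, with adjusted p up to 0.283 without knockdown replicate 1. The GDNF call was also lost with no filter on low counts (adjusted p = 0.0792). MAZ differed by 0.06 (adjusted p = 0.456) and SPIN4 by 0.37 (adjusted p = 0.000118). Limma called 3399 of 15774 genes, 1743 higher and 1656 lower with EML631, of which 143 and 96 exceeded 1.5-fold and 25 and 22 exceeded 2-fold. Over all tested genes, groups did not overlap for 37.5%, where chance gives 10%.

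Camera called no other list between the treatments, at adjusted p from 0.0586 to 0.988. The counts of higher and lower genes, followed by those adjusted over the list alone, were 7 and 2 of 18 (8 and 4) for metalloproteinases, 9 and 14 of 43 (11 and 15) for lysosomal genes, 6 and 2 of 20 (7 and 2) for heat shock, 2 and 7 of 28 (3 and 7) for RNA polymerase I, 3 and 0 of 16 (3 and 0) for Wnt targets, 0 and 6 of 24 (0 and 6) for MAPK feedback, 4 and 6 of 30 (6 and 8) for p53 targets and 2 and 8 of 27 (2 and 9) for the amplicon. They were 1 and 4 of 12 (1 and 4) for adipocyte differentiation, where PPARG differed by -0.51 and PLIN2 by -0.56, 7 and 1 of 25 (7 and 1) for the unfolded protein response, 4 and 5 of 35 (4 and 5) for the amino acid response, 5 and 3 of 25 (6 and 6) for NRF2 targets and 1 and 1 of 8 (1 and 1) for metallothioneins. RNA interference machinery gave 0 and 1 of 13 (0 and 1), histone methylation enzymes 4 and 1 of 20 (4 and 1), GDNF-RET signalling 3 and 0 of 6 (3 and 0), spindlins 1 and 0 of 4 (1 and 0), epithelial markers 1 and 2 of 9 (1 and 2), blood and endothelial markers 0 and 1 of 8 (0 and 0) and muscle and neural markers 0 and 2 of 5 (0 and 2).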

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

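All tests of explanations below were chosen after the list results, the principal components and the SPIN1 levels had been seen, and for handling and culture state the value itself was already known. Groups of 3 libraries are too small for a search for single outlying libraries. A pair of lists stood out because camera called them in opposite directions in the 2 treatments and called the direct difference. With an estimated correlation none of these calls held: the adjusted p for EML631 and the knockdown was 0.174 and 0.15 for hypoxia and glycolysis and 0.366 and 0.271 for cholesterol synthesis. For cholesterol synthesis the EML631 call was lost without control replicate 3 (adjusted p = 0.0596) or EML631 replicate 3 (0.0595). Hypoxia and glycolysis genes differed between EML631 and the knockdown by a median of -0.39 in log2, and cholesterol synthesis genes by a median of -0.204; with an estimated correlation the adjusted p of the direct difference was 0.182 and 0.22.

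Hypoxia and glycolysis genes were lower with EML631 and higher in the knockdown than in the controls. No single treated library accounts for the difference between the treatments: with each of the 6 treated libraries left out in turn, the median difference nearest to 0 was -0.345. Bias by GC content or gene length is argued against as the whole cause, because removing a smooth trend on both from each library left a median of -0.396; 85.5% of the tested genes and 100% of the list had both values. What stays open is the state of the cultures at harvest, such as density, oxygen or medium, which the labels do not give. Transfection of the knockdown libraries and any solvent of EML631 stay open too, as no group received either alone. None of these can be told apart from the treatments, and the median difference of -0.39 could come from the treatments or from any of these. The groups also differ in time, 3 days against 24 hours.

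Interferon-stimulated genes were lower than in untreated cells in both treatments. No single control library carries this: with each control left out, the median log2 fold change nearest to 0 was -0.711 with EML631 and -0.391 in the knockdown, against -0.72 and -0.44 with all. Scaling does not either, since under quantile normalization the medians were -0.708 with EML631 and -0.43 in the knockdown. Total scaling gave -0.711 and -0.429, but it can shift little because the scaled totals are nearly equal. The FPKM table gave -0.673 and -0.407, but it carries the same scaling as the counts and so does not test it. Handling that both treated groups had and the untreated controls lacked stays open, as no mock-treated group is among the samples. The median difference of -0.289 between the treatments speaks only against handling alike in both as the whole cause, and with an estimated correlation that difference had an adjusted p of 0.318. A shared consequence of losing SPIN1 function is the biological candidate explanation and was not separated from handling.

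Knockdown replicate 2 held 72.2% of the control level of SPIN1, against 40.1% and 34.3% in the others. Untransfected cells or control RNA in that library would shrink the changes of other genes along with that of SPIN1. The log2 fall of SPIN1 was 0.331 of that of the other libraries. Mixing acts on levels rather than on log2 values, so this share is too low a guide for genes with small changes. Over all tested genes, the covariance of replicate 2 with the other knockdown libraries, computed with separate controls, was 0.807 of theirs with each other. This ratio ran from 0.745 to 0.872 over the choices of controls. Most of the shared difference from untreated cells was thus present, which argues against control RNA as the whole cause. Untransfected cells stay open: in the same dish they would share the effects of reagent and culture state, which this covariance includes. An EML631 library under the wrong label is argued against as well: of 3430 genes called between EML631 and the other knockdown libraries, replicate 2 lay nearer to the knockdown at 74.4%. A candidate explanation is that the wider response did not follow the SPIN1 mRNA left at harvest, as for an effect of the siRNA on other transcripts or an earlier fall of the protein; neither was tested.

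The 6 libraries of each comparison can be split in 10 ways, which is too few for a share under 0.05. The real split called 3489 genes for EML631 against control and the highest other split 0. For the knockdown against control these numbers were 3353 and 1, and for EML631 against the knockdown 3399 and 1. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real one. Each other split puts libraries of both groups on each side, which widens the spread wherever the groups differ. Its low number of calls was therefore fixed in advance and gives the real split no support.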

How the results depend on the processing

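Total scaling, quantile normalization, pseudocounts of 0.5 and 10 and voom were added after the data were seen. The planned DESeq2 fit and the edgeR fits with RLE factors or library totals were not run, because they take raw counts and the deposited values are scaled. They were not tried on the values divided by the step, on which voom was run. The counts of called genes stayed within 1.5 times of the main values under all alternatives but the FPKM table without a filter, which called 2084 genes for EML631, 2130 for the knockdown, 2091 for their difference and 871 genes shared in direction, with more low genes tested. Genes of opposite direction, 209 in the main fit, varied more, at 65 in that table, 111 on log2(FPKM + 1) with its filter and 119 to 247 with 1 library left out. With 1 library left out the called genes ranged from 2593 to 3709, from 2419 to 3591 and from 2312 to 3933, and shared genes from 1126 to 1576. SPIN1 in the knockdown kept its log2 fold change of -1.12 but not its call with the 6 libraries alone (-1.12, adjusted p = 0.0946) and with the replicate block (-1.12, adjusted p = 0.0575); with 1 library left out the fold change ranged from -1.45 to -0.906, and the call was lost unless the library left out was knockdown replicate 2. With fewer libraries less is left to estimate the spread; the cause of the other losses was not tested.

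Replicate numbers paired the samples weakly at most: the correlations of deviations between same-numbered libraries ran from -0.0609 to 0.128, and 5 of the 9 libraries matched their own number best. The block gave 3654, 3480 and 3604 calls in the 3 comparisons, against 3489, 3353 and 3399 without it, and 1551 shared genes. A weak effect shared by libraries of the same number is not excluded.

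With an estimated correlation camera called 0 lists in each of the 3 comparisons. Of 39 list calls, 34 held under all other alternatives; the others were cholesterol synthesis, metalloproteinases and p53 targets for EML631, RNA interference machinery for the knockdown and NF-kB genes for the direct difference. Of 382 calls of named genes, 323 held under all alternatives in which the gene was tested, 59 were lost under at least 1 and 0 reversed. Some named genes did not pass the filter of the FPKM table, so their calls were not checked on the filtered FPKM values. Total scaling moved the share of higher calls from 49.8% to 56.6% for EML631 and from 48.5% to 55.6% for the knockdown. In the simulations, which changed far fewer genes than were called in the data, the smallest changes were often missed.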

Other observations

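AHR and 11 of 13 tested genes from a list of its targets were lower in the knockdown; the list was put together only after the values of its genes, and of others such as oxidative stress genes that were not put in the list, had been looked up. AHR, the aryl hydrocarbon receptor, is a ligand-activated transcription factor that induces cytochrome P450 genes. It was at 86.1 ± 6.53 CPM in the knockdown against 115 ± 0.491 in the controls (SD, n = 3; log2 fold change -0.44, SE 0.043, adjusted p = 4.59e-08). With EML631 it was at 105.1 ± 2.29 CPM (SD, n = 3; log2 fold change -0.14, SE 0.043, adjusted p = 0.0178). CYP1B1 fell by 1.16 in log2, AHRR, a repressor of the receptor, by 0.85, TIPARP by 0.66 and the transporter ABCG2 by 0.86. ALDH1A3 fell by 0.82 and LRRN3 by 0.81. NQO1, also a target, had a log2 fold change of -0.02 (adjusted p = 0.825), and ARNT, the partner of AHR, one of -0.06 (adjusted p = 0.441).

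Of 13 tested targets 11 were lower in the knockdown and 0 higher, with a median log2 fold change of -0.817. Among the 11, CYP1A1, UGT1A6 and SERPINB2 had means below 5 CPM in every group. With EML631 6 were lower and 1 higher (median -0.31), and 8 were higher with EML631 than in the knockdown (median 0.45). CYP1B1 was not among the called ones with EML631 (log2 fold change -0.08, limma's adjusted p = 0.277). Camera's p for the knockdown was 4.22e-15, and 0.000164 with an estimated correlation. For EML631 it was 4.44e-05, and 0.00497 with an estimated correlation. None of these is evidence of its own, because the genes were chosen from the same data. A hypothesis is that AHR activity may be lower after the siRNA. The 11 lower targets would also be seen if the siRNA acted on AHR mRNA itself or if transfection lowered AHR. A non-targeting siRNA, which is not among these samples, would address transfection only. It would not tell an effect of this siRNA on AHR mRNA from loss of SPIN1. Neither transfection nor an effect of the siRNA on AHR mRNA would account for the smaller fall with EML631, which was not explained. Handling or culture state that the controls did not share stays open for both treatments.

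MDM2, the amplified oncogene of this tumour type, was at 14790 ± 431 CPM in the controls, 14220 ± 275 with EML631 and 14780 ± 186 in the knockdown (SD, n = 3), and took up 1.39% to 1.53% of a library. It fell by 0.07 in log2 with EML631 (adjusted p = 0.0212).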
